A study of Mus musculus with 17 samples.

How the data were processed

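Total RNA from whole small intestine of 17 mice was labelled and hybridised to Affymetrix mouse genome arrays, 1 array per mouse, per the labels. Each array is a biological replicate of its group (7 WT, 3 Apc, 4 Kras and 3 ApcKras). Per the submitters' processing notes, RMA, affy and limma were used, with no version, role or order given. The deposited values are probeset intensity on a linear scale, normalised between arrays by the authors before deposit, since the arrays share nearly the same distribution. They run from -1843 to 33080, and 374 of 45101 probesets hold a value at or below 0 on some array. The design had been written for log2 values, so the linear values were raised to a floor of 32 and then taken to log2, where the floor is 5. At gene level 13.1% of the values were at the floor.

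A mark of a further step that no label records was read from the values. Of the 35 splits of the WT arrays into 4 and 3, that into WT 1 to 4 and WT 5 to 7 had the closest means, with a root mean square difference of 29.48 intensity units over probesets, against 61.13 for the next and 130 for the widest. The other arrays were placed by genes silent in 1 sex, against WT arrays alone. Xist, a transcript of the inactive X chromosome, had a median of -560.7 on the males of WT 1 to 4 and 815.5 on WT 5 to 7, and was at -497.1 on Kras 1 and 655.5 to 820.4 on the male Apc and ApcKras arrays. Eif2s3y, of the Y chromosome, was at 420 and 420.2 on the females WT 2 and WT 4, 388.1 to 394.7 on Kras 2 to 4 and -363.7 on ApcKras 2, for which WT 5 to 7 hold no female to compare. The first batch holds WT 1 to 4 and all Kras arrays, the second WT 5 to 7 and all Apc and ApcKras arrays. Sex, which the labels do not give, was read from Xist.

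Of the probesets, 35890 are listed with a gene in the annotation used, 34958 with a single gene and 932 with several, 9211 are not listed, and 64 are controls of the maker. An Entrez identifier was found for 34754 of those with a single gene. Each of the 18194 genes was represented by its probeset with the highest mean over all arrays, and 9012 genes had more than 1 probeset. No filter on low values was applied. A value at or below 0 was held by 154 of these probesets. A fold of a single gene with an array at the floor in the groups compared is given only as a bound, apart from the differences of Kras effects of Anxa10, Gzmb, Prss2 and Tek, which depend on the floor. For Mcm6 in ApcKras against WT and against Kras, and for Sntb1 and E2f1 in ApcKras against Kras, another probeset passed in the opposite direction.

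All arrays entered 1 linear model with a mean per group in limma 3.58.1 under R 4.3.3, so that the groups share an estimate of the spread. Each comparison is a contrast of that model, tested with limma's moderated statistic (empirical Bayes) and Benjamini-Hochberg adjustment over all genes, with a threshold of 0.05, and all tests are two-sided. Adjusted p values of single genes in the text come from this fit. Errors of log2 folds are standard errors of the contrast, and errors of group means are SD between arrays. Without batch, sex or pairing in the labels, no covariate was used, and the fit with the batch as a term was added after the data were seen. Correlations of log2 folds are across genes, with a standard error from a jackknife over arrays and no p. Expected overlaps are those of independent calls. Plots were drawn with matplotlib 3.10.9.

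Before the data were examined, 31 gene lists of cell types, pathways and possible contaminants were fixed from general knowledge, and so were the tests, the alternatives not called added below and the rule for naming genes. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the lists within each of the 6 contrasts, 186 tests in all. The number of members past the threshold was also taken with adjustment over the list alone. The naming rule takes, per comparison, Apc, Kras, Vil1, Slc7a5 and Slc3a2, the 6 largest rises and falls among genes past the threshold whose arrays do not overlap between the groups (overlap was allowed for the difference of Kras effects), and up to 4 members of a described list by size of fold. Not every gene that the rule gives is named, and the further pancreatic genes were listed after the first had been seen.

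Alternatives changed a single choice each. They were a repeat quantile normalization, centring on array medians, leaving out the 30% dimmest genes, the mean of a gene's probesets, every probeset alone, leaving out probesets marked as matching several transcripts, a variance trend with robust estimation, array weights, only the arrays compared, the replicate number as a block, a log2 fold of at least 1, an adjusted p of 0.01, leaving out each array, and for lists an estimated correlation, camera on ranks and fry, which tests whether genes move on balance in a common direction without reference to other genes. Added after seeing the data were floors of 16 and 64, leaving out probesets with a value at or below 0, the batch term, a sex term, and leaving out WT 6, Apc 1 and Kras 1 together.

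The fit was tested on simulated data of 18194 genes with 200 changed. At a true log2 fold of 2 it recovered 93.9% to 100% over the contrasts, at 1 62.7% to 86.6%, and at 0.5 22.4% to 46.3%. False calls were at most 19 of 188 calls (Apc against WT). Their share was above the threshold except for the difference of Kras effects (6 of 131). Camera called both shifted lists in each contrast and 0 of 29 others, but correlated genes were not tested. Depth has no meaning for arrays. Kras messenger and probesets without a single gene were left out of the gene tests.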

Results

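Gene expression was measured on whole small intestine of C57BL/6J mice with Affymetrix oligonucleotide arrays, which read messenger RNA by hybridisation to probesets. All mice carried villinCreER, a tamoxifen-inducible Cre recombinase driven by the promoter of villin, a protein of the brush border of intestinal epithelium. The 17 arrays fell into 4 groups: control intestine (WT, n = 7), intestine with floxed alleles of the tumour suppressor Apc (Apc, n = 3), intestine with an activated allele of the GTPase Kras (Kras, n = 4), and intestine with both (ApcKras, n = 3). Median intensity per array lay between 115 and 120.7. Between 17.8% and 20.1% of the values of an array were at or below the floor of 32, and the number of arrays limits the precision. Correlation of log2 intensity across genes had a median r of 0.9895 among WT arrays, 0.9839 among Apc, 0.9814 among Kras and 0.9861 among ApcKras, against 0.9637 between arrays of different groups, where genes are not independent replicates. The first principal component held 43.5% of the variance and the second 14.6%.

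**Figure D1:**
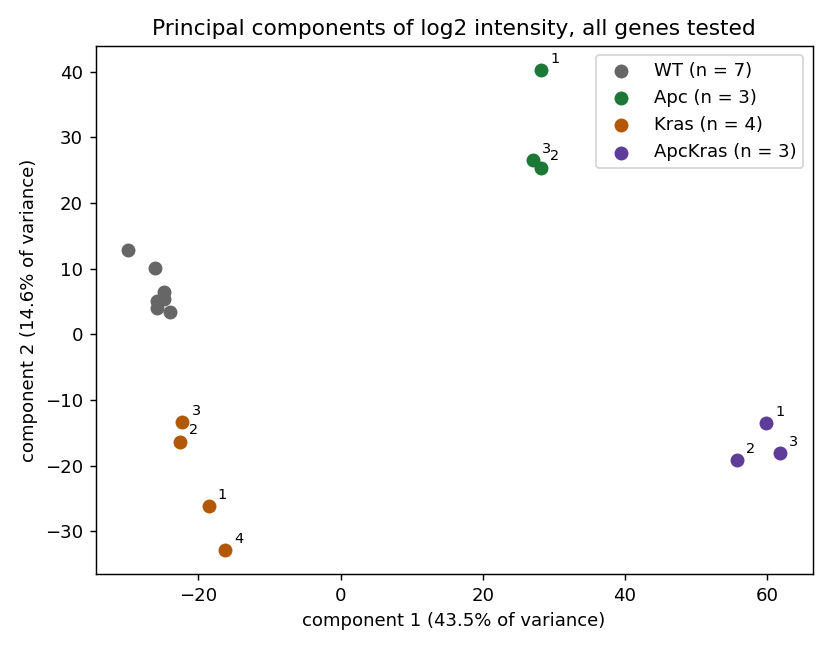
Principal components 1 and 2 of log2 intensity over all genes tested, with the percent of variance on each axis. Each point is an array, coloured by group, and the arrays other than WT carry their replicate number. Component 1 holds 43.5% of the variance, and on it the ApcKras arrays (55.8 to 61.8) do not overlap those of WT (-29.9 to -24).

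The level of Apc messenger did not mark the deletion. Apc averaged 10.04 ± 0.10 log2 intensity (SD, n = 7) in WT and 10.10 ± 0.07 (n = 3) in Apc intestine, a log2 fold of 0.06 ± 0.07 (SE, adjusted p = 0.617). ApcKras averaged 10.06 ± 0.13 (n = 3). The labels do not give the deleted exons, and probes outside them would read a shortened messenger as before, so this value does not check the labels. Of the 4 Apc probesets, the brightest gave these values, and another fell in Apc intestine (-0.17 ± 0.06, adjusted p = 0.0436). In Kras intestine Apc rose by 0.25 ± 0.06 on the log2 scale, a call that ended without Kras replicate 1 (0.0632) or Kras replicate 4 (0.0598). Kras messenger was not analysed here, because no probeset carries its name in the annotation used. Vil1, which encodes villin, fell in Apc intestine (-0.49 ± 0.05) and in ApcKras intestine (-0.71 ± 0.05), while in Kras intestine its log2 fold was -0.11 ± 0.05 (adjusted p = 0.19). From here on, a value in brackets after a gene is its log2 fold ± SE, and a gene said to have risen or fallen passed the adjusted p threshold of 0.05 over all genes. The values carry the mark of an unstated adjustment between WT 1 to 4 with Kras, and WT 5 to 7 with Apc and ApcKras. List counts with this batch as a term are given where lower by more than 1.5 times. Both WT means nearly coincide, so passing with this term does not test a batch. Whether probes for Prss2, Cela3b, Cyp2c65, Ugt2b5, Defa3, Clca3b, Adh6a and Reg3a tell apart the members of their gene families was not tested, so these symbols are uncertain.

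Comparing Apc with WT intestine (n = 3 and 7) asked what loss of Apc, the scaffold that keeps beta-catenin low, does to the tissue. Among stem cell and Wnt pathway genes that rose were Sox9 (2.37 ± 0.14), a transcription factor of crypt progenitors, Tnfrsf19 (2.75 ± 0.21), a receptor of crypt stem cells, and Rnf43 (2.10 ± 0.12), a ligase that removes Wnt receptors. Lgr5 (1.77 ± 0.30, adjusted p = 0.000928), the marker of crypt base stem cells, and Ascl2 (1.70 ± 0.38), their transcription factor, rose as well. Cybrd1, a duodenal ferric reductase, rose by 4.03 ± 0.34 with no overlap between the arrays of the groups. Lower were Slc5a4a (-3.49 ± 0.49), of the sodium and glucose cotransporter family, Noct (-3.03 ± 0.34), a clock-regulated phosphatase of NADP(H), and Cd79a (-2.93 ± 0.30), a part of the B cell receptor. A move of the fold by more than 1.5 times was seen without Apc replicate 2 for Slc5a4a (-4.11).

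Of the 19 intestinal stem cell markers, 17 rose (18 adjusted over the list alone), and camera called the list higher (adjusted p = 1.2e-15, 0.00637 with an estimated correlation). Among the 28 Wnt targets, 19 rose and 1 fell (21 and 1 adjusted over the list alone, 18 and 0 with the batch term), and camera called the list higher (adjusted p = 6.91e-14, 0.00637 with an estimated correlation). Prox1 (2.41 ± 0.17), a transcription factor of lymphatic endothelium also in the Wnt list, rose. Of the 30 ribosome biogenesis genes, 23 rose (25 adjusted over the list alone), and camera called the list higher (adjusted p = 6.91e-14, 0.12 with an estimated correlation). Wdr43 (0.82 ± 0.08) and Nop56 (0.76 ± 0.09), which act in processing of ribosomal RNA, were examples. Of the 29 cell cycle genes, 17 rose (22 adjusted over the list alone), and camera called the list higher (adjusted p = 3.98e-09, 0.22 with an estimated correlation). Mcm6 (1.22 ± 0.19) and Mcm5 (0.87 ± 0.19), subunits of the replicative helicase, were higher. Of the 25 ERK pathway output genes, 11 rose and 3 fell (12 and 3 adjusted over the list alone, 7 and 1 with the batch term), and camera called the list higher (adjusted p = 0.00844, 0.266 with an estimated correlation). Etv4 (1.27 ± 0.13), Dusp4 (1.19 ± 0.18) and Myc (1.13 ± 0.12) rose, and Myc also belongs to the Wnt list. Slc7a5, which carries large neutral amino acids, had a log2 fold of 0.39 ± 0.16 (adjusted p = 0.0851). Slc3a2, its partner subunit, fell (-0.62 ± 0.20). This call ended without Apc 1 (0.109), 2 (0.104) or 3 (0.0635), or WT 3 (0.0567), 4 (0.0562), 5 (0.0559) or 7 (0.0564).

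Among lists of epithelial cells, those of enterocytes and enteroendocrine cells were called lower, and those of Paneth, goblet and tuft cells were not called. Of the 29 absorptive enterocyte markers, 17 fell (17 adjusted over the list alone), and camera called the list lower (adjusted p = 2.5e-07, 0.123 with an estimated correlation). Anpep (-0.91 ± 0.14), a brush border aminopeptidase, and Slc6a19 (-0.99 ± 0.20), a neutral amino acid transporter, were lower. Of the 24 xenobiotic and retinoid metabolism genes, 12 fell (13 adjusted over the list alone), and camera called the list lower (adjusted p = 2.58e-05, 0.184 with an estimated correlation). Ugt2b5 (-2.50 ± 0.50), a glucuronosyltransferase, was the example. Of the 22 enteroendocrine cell markers, 6 fell (7 adjusted over the list alone, 3 with the batch term), and camera called the list lower (adjusted p = 0.00378, 0.123 with an estimated correlation). Tph1 (-1.46 ± 0.15), the enzyme of serotonin synthesis, and Pcsk1 (-1.52 ± 0.23), a prohormone convertase, were lower. Among the 14 Paneth cell markers, 4 rose and 1 fell (6 and 1 adjusted over the list alone, 2 and 0 with the batch term), and camera did not call the list (adjusted p = 0.052). Fgfrl1 (1.40 ± 0.25) and Ang4 (1.24 ± 0.29), an antimicrobial ribonuclease of Paneth cells, rose, and the list passed with the batch term (adjusted p = 0.0465). Of the 18 goblet cell markers, 2 rose and 6 fell (2 and 6 adjusted over the list alone, 0 and 4 with the batch term), and camera did not call the list (adjusted p = 0.0615). Fcgbp (-0.59 ± 0.09), a mucus protein, was lower.

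Lists of B, T and macrophage markers were called lower, and that of neutrophil and acute inflammation genes was not called. Of the 15 B and plasma cell markers, 11 fell (13 adjusted over the list alone, 6 with the batch term), and camera called the list lower (adjusted p = 1.74e-06, 0.167 with an estimated correlation). Of the 16 T and NK cell markers, 7 fell (10 adjusted over the list alone, 4 with the batch term), and camera called the list lower (adjusted p = 1.79e-05, 0.22 with an estimated correlation). Cd3e (-1.47 ± 0.26), a chain of the T cell receptor complex, Gzmb (-1.96 ± 0.29), a protease of cytotoxic cells, and Csf1r (-0.59 ± 0.14), the macrophage growth factor receptor, were examples. Of the 15 B and plasma cell members, 10 were highest on WT 6 among WT arrays, and 5 held a value at or below 0 in Apc. The MHC class II call ended without probesets holding such a value (0.0527) and without WT 6, Apc 1 and Kras 1 (0.0676). Camera also called lower the macrophage and myeloid markers (6 of 16 fell, 10 adjusted over the list alone), MHC class II genes (3 of 8, 5 alone), endothelial markers (5 of 14, 1 rose, 9 alone, 3 and 1 with the batch term), cholesterol synthesis genes (3 of 17, 3 alone, 1 with the batch term), fatty acid oxidation and PPAR target genes (5 of 21, 6 alone, 2 with the batch term) and interferon response genes (4 of 20, 4 alone, 1 with the batch term), with adjusted p between 0.00071 and 0.036, and adjusted p = 0.123 to 0.553 with an estimated correlation. Tek (-1.90 ± 0.17), the angiopoietin receptor, fell, whereas Prox1, of the same list, rose. Camera also called higher the translation initiation and elongation factors (6 of 19, 2 fell, 7 alone, 3 and 2 with the batch term), with adjusted p = 0.036, and adjusted p = 0.296 with an estimated correlation.

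Digestive enzymes of the pancreas were higher in the Apc group. Of the 9 pancreas, adipose and blood contaminant markers, 5 rose (5 adjusted over the list alone), and camera called the list higher (adjusted p = 0.00247, 0.22 with an estimated correlation). Cpa1 (4.36 ± 0.61), a carboxypeptidase, Sycn (3.73 ± 0.66), a zymogen granule protein, Cela2a (3.52 ± 0.58) and Cela3b (3.40 ± 0.58), elastases, are made by acinar cells of the pancreas. Their levels stood apart on Apc 1. Cpa1 was at 13.04 log2 intensity there, 9.25 on Apc 2 and 9.22 on Apc 3, against a WT mean of 6.14 ± 0.37 (SD, n = 7). The fold moved by more than 1.5 times without Apc replicate 1 for Cpa1 (3.09), Sycn (2.48), Cela2a (2.28) and Cela3b (2.18), without Apc replicate 2 for Cpa1 (4.99), Sycn (4.35), Cela2a (4.15) and Cela3b (4.00) and without Apc replicate 3 for Cpa1 (5.00), Sycn (4.36), Cela2a (4.14) and Cela3b (4.03). Without Apc replicate 1 the median log2 fold of the 5 acinar members was 3.09, against 4.36 with it.

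Across all genes, limma called 2169 higher and 2257 lower in Apc intestine at adjusted p 0.05, of 18194 tested. With the batch as a term, which sets the Apc arrays against WT 5 to 7 of their own batch, 1270 were higher and 1356 lower. Of 35 named genes that passed, 34 did so with the batch term, not Slc3a2. Single gene calls ended for Mcm5 and Ang4 with the mean of a gene's probesets, for Mcm5 and Ang4 without probesets of shared sequence, for Slc3a2 with a sex term. The cholesterol call ended without Apc replicate 1 (0.0525), without WT replicate 5 (0.0641) and with fry (0.0985). That of fatty acid oxidation ended with the dimmest genes left out (0.0538) and with the mean of a gene's probesets (0.058), that of interferon without Apc replicate 2 (0.119), without WT replicate 1 (0.0753), without WT replicate 2 (0.0663), without WT replicate 5 (0.0702), with fry (0.121) and with a sex term (0.06), and that of translation without Apc replicate 2 (0.0607), without Apc replicate 3 (0.0865), without WT replicate 3 (0.0525), with the dimmest genes left out (0.13) and after a repeat quantile normalization (0.074). In all, 18 of 31 lists were called, of which 2 held with an estimated correlation, and 19 passed with the batch term. The 13 enteric neuron and glia markers, never called in any of the 6 comparisons, were among the 13 lists without a call, with camera adjusted p between 0.052 and 0.978. Past the threshold only under other settings, with the number of settings and the lowest adjusted p in brackets, were the goblet (7, 0.00407), Paneth (7, 0.0132), p53 (5, 0.00519), fibroblast (4, 0.0131), ATF4 (2, 0.0187), tuft (2, 0.00445) and amino acid transporter (1, 0.00702) lists. Signs differed for the glycolysis genes (median 0.14, mean -0.05, test up) and tuft cell markers (median 0.19, mean -0.13, test down).

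Kras against WT intestine (n = 4 and 7) asked what the activated Kras allele does with Apc intact. Fabp6, the ileal bile acid binding protein, rose by 3.84 ± 0.58 (adjusted p = 0.00249), and Fgf15, the hormone that ileal enterocytes release in response to bile acids, by 2.46 ± 0.48. Kras 1 stood apart for Fabp6, at 13.82 log2 intensity against a median of 10.18 on the other Kras arrays. Also higher were Ddah1 (2.73 ± 0.22), which degrades inhibitors of nitric oxide synthase, Mgat4c (3.05 ± 0.43), a glycosyltransferase, and Etv4 (1.40 ± 0.12), a transcription factor induced by ERK signalling. Nav2 (-1.56 ± 0.17), Col6a4 (-1.70 ± 0.34), a collagen chain, Akr1c14 (-1.93 ± 0.39), a hydroxysteroid dehydrogenase, and Reg3a (-2.21 ± 0.46), an antimicrobial lectin, fell. A move of the fold by more than 1.5 times was seen without Kras replicate 1 for Fabp6 (2.93), Fgf15 (1.69), Mgat4c (2.43) and Reg3a (-1.48).

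Of the 17 cholesterol synthesis genes, 10 rose (14 adjusted over the list alone, 5 with the batch term), and camera called the list higher (adjusted p = 6.08e-10, 0.143 with an estimated correlation). Nsdhl (0.98 ± 0.13), Fdps (0.98 ± 0.20) and Lss (0.92 ± 0.17) encode steps of the pathway. Of the 17 hypoxia and angiogenesis genes, 5 rose (10 adjusted over the list alone), and camera called the list higher (adjusted p = 1.58e-06, 0.0487 with an estimated correlation). Car9 (1.20 ± 0.17), a carbonic anhydrase, and Bnip3 (1.16 ± 0.22), a mitochondrial protein, are induced by low oxygen. Of the 17 glycolysis genes, 4 rose (9 adjusted over the list alone), and camera called the list higher (adjusted p = 2.6e-05, 0.143 with an estimated correlation). Pdk1 (0.88 ± 0.10), which inhibits pyruvate dehydrogenase, and Slc2a1 (0.70 ± 0.07), a glucose transporter, rose. Of the 30 ribosome biogenesis genes, 10 rose (14 adjusted over the list alone, 6 with the batch term), and camera called the list higher (adjusted p = 4.39e-08, 0.143 with an estimated correlation). Bysl (0.60 ± 0.10) and Nop16 (0.56 ± 0.11) were examples. Of the 25 ERK pathway output genes, 4 rose (9 adjusted over the list alone), and camera called the list higher (adjusted p = 0.00013, 0.143 with an estimated correlation). Besides Etv4, Emp1 (0.69 ± 0.11), Spred2 (0.38 ± 0.07) and Spry2 (0.33 ± 0.06) rose, and Spred2 and Spry2 encode feedback inhibitors of the pathway. Of the 23 ATF4 and amino acid synthesis genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone, 3 and 0 with the batch term), and camera called the list higher (adjusted p = 0.00845, 0.267 with an estimated correlation). Eif4ebp1 (1.34 ± 0.16), a repressor of cap-dependent translation initiation, and Psat1 (0.85 ± 0.17), of serine synthesis, were higher. Of the 24 amino acid transporters, 4 rose (4 adjusted over the list alone, 1 with the batch term), and camera did not call the list (adjusted p = 0.443). Slc7a5 (0.55 ± 0.14) was higher. This call ended without Kras 2 (0.0749) or 4 (0.101), or WT 2 (0.0542), 3 (0.0641), 4 (0.0572), 6 (0.0523) or 7 (0.0523). Slc3a2 had a log2 fold of -0.29 ± 0.18 (adjusted p = 0.372). Camera also called higher the translation initiation and elongation factors (3 of 19, 6 alone), with adjusted p = 0.0146, and adjusted p = 0.239 with an estimated correlation.

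Lists of stem cell, enteroendocrine, enterocyte, T, B and macrophage markers were called lower, while those of Paneth cells, MHC class II and neutrophils were not called. Of the 22 enteroendocrine cell markers, 3 fell (1 higher and 5 lower adjusted over the list alone), and camera called the list lower (adjusted p = 2.6e-05, 0.0488 with an estimated correlation). Chga (-0.97 ± 0.16) and Chgb (-0.64 ± 0.07), granins of secretory granules, fell. Of the 19 intestinal stem cell markers, 1 rose and 5 fell (3 and 12 adjusted over the list alone, 0 and 0 with the batch term), and camera called the list lower (adjusted p = 0.000224, 0.143 with an estimated correlation). Of the 29 absorptive enterocyte markers, 2 rose (2 adjusted over the list alone), and camera called the list lower (adjusted p = 0.0116, 0.339 with an estimated correlation). The members of that list that rose were Fabp6 and Slc10a2, the ileal bile acid transporter, which went against the list. Of the 16 T and NK cell markers, 2 fell (5 adjusted over the list alone), and camera called the list lower (adjusted p = 8.06e-06, 0.166 with an estimated correlation). Cd8b1 (-0.90 ± 0.17) and Cd4 (-0.67 ± 0.13), coreceptors of T cells, fell. Cd14 (0.80 ± 0.16), a receptor for bacterial lipopolysaccharide, rose, against Csf1r (-0.69 ± 0.13) and Lyz2 (-0.69 ± 0.14), which fell. Fbln1 (-0.91 ± 0.18) and Col6a1 (-0.62 ± 0.12), of the extracellular matrix, fell. Camera also called lower the xenobiotic and retinoid metabolism genes (2 of 24, 6 alone, 0 with the batch term), Wnt targets (2 of 28, 2 alone, 0 with the batch term), B and plasma cell markers (3 of 15, 5 alone), macrophage and myeloid markers (4 of 16, 1 rose, 6 alone), fibroblast and matrix markers (4 of 14, 9 alone, 2 with the batch term), interferon response genes (1 of 20, 2 alone, 0 with the batch term) and endothelial markers (0 of 14, 0 alone), with adjusted p between 2.6e-05 and 0.01, and adjusted p = 0.143 to 0.277 with an estimated correlation.

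At adjusted p 0.05, 877 genes were higher and 439 lower in Kras intestine. The split was less uneven after a repeat quantile normalization, with 608 higher and 514 lower, and more uneven with arrays centred on their medians, with 1244 and 383. With the batch term, 301 were higher and 133 lower, from Kras against WT 1 to 4 of its batch. Without Kras replicate 4 the count was 729, and with a sex term it was 711. Of 34 named genes that passed, 31 did so with the batch term, not Apc, Reg3a and Slc7a5. Single gene calls ended for Slc7a5 with only the arrays compared, for Emp1, Spred2 and Spry2 with the mean of a gene's probesets, for Apc, Fdps and Slc7a5 with WT 6, Apc 1 and Kras 1 left out, for Apc and Slc7a5 with a sex term, for Apc and Slc7a5 after a repeat quantile normalization. Of 31 lists, 18 were called, 2 held with an estimated correlation and 18 passed with the batch term. The enterocyte call ended without Kras replicate 1 (0.271), with array weights (0.0848), with fry (0.184) and with WT 6, Apc 1 and Kras 1 left out (0.15). The B and plasma cell call ended with fry (0.0882) and with WT 6, Apc 1 and Kras 1 left out (0.0516), the endothelial call without Kras replicate 2 (0.0503), the interferon call with fry (0.0757), and the translation call without Kras replicate 4 (0.0739), with the dimmest genes left out (0.0634) and with array weights (0.0543). The remaining 13 gave no call, with camera adjusted p between 0.055 and 0.775. Past the threshold only under other settings were the MHC class II (14, 0.00369), Paneth (8, 0.00148), goblet (4, 0.000131), neutrophil (4, 0.0213), fetal (1, 0.0404) and contaminant (1, 0.0398) lists. Signs differed for the fatty acid oxidation and PPAR target genes (median -0.07, mean 0.05, test down) and cell cycle genes (median -0.01, mean 0.01, test down).

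ApcKras against WT intestine (n = 3 and 7) joined both alleles. Krt23 (4.26 ± 0.20), a keratin, Cybrd1 (4.33 ± 0.34), Serpinb5 (3.95 ± 0.45), the serpin maspin, S100a14 (3.68 ± 0.33) and Ddah1 (3.37 ± 0.24) rose, with no overlap between the arrays of the groups. Psat1 (2.99 ± 0.19), Asns (2.08 ± 0.14), the asparagine synthetase, and Slc7a5 (2.06 ± 0.16, adjusted p = 3.48e-07) rose. Slc7a11, the cystine transporter, was at the floor on some WT arrays, and was at least 12.4-fold higher. Sox9 (2.65 ± 0.14), Cd44 (2.26 ± 0.15), Myc (1.99 ± 0.12) and Fosl1 (2.33 ± 0.12), an AP-1 subunit induced by ERK, were higher too. Bnip5 (-5.03 ± 0.44), Adh6a (-3.77 ± 0.53), an alcohol dehydrogenase, Slc13a1 (-3.43 ± 0.74), the sulfate transporter, and Casp4 (-3.50 ± 0.45), an inflammatory caspase, fell. The fold of Bnip5 moved by more than 1.5 times without ApcKras 1 (-4.35) or 2 (-5.80). That of Adh6a did so without ApcKras 1 (-4.37) or 3 (-2.94).

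Of the 30 ribosome biogenesis genes, 29 rose (30 adjusted over the list alone), and camera called the list higher (adjusted p = 1.85e-18, 0.0674 with an estimated correlation). Nop16 (1.47 ± 0.12) and Gnl3 (1.37 ± 0.14), the nucleolar protein nucleostemin, were examples. Of the 29 cell cycle genes, 26 rose (27 adjusted over the list alone), and camera called the list higher (adjusted p = 6.62e-11, 0.131 with an estimated correlation). Tpx2 (1.17 ± 0.11), of the mitotic spindle, and Cdk1 (1.07 ± 0.09) were examples. Of the 23 ATF4 and amino acid synthesis genes, 18 rose (18 adjusted over the list alone), and camera called the list higher (adjusted p = 5.94e-10, 0.0674 with an estimated correlation). Of the 25 ERK pathway output genes, 17 rose (18 adjusted over the list alone), and camera called the list higher (adjusted p = 2.3e-07, 0.0697 with an estimated correlation). Etv4 (2.74 ± 0.13) and Phlda1 (1.66 ± 0.23) rose beside Fosl1. Of the 17 fetal and regenerative epithelium genes, 10 rose and 2 fell (10 and 2 adjusted over the list alone, 10 and 1 with the batch term), and camera called the list higher (adjusted p = 0.000701, 0.183 with an estimated correlation). Anxa3 (2.97 ± 0.23), Il1rn (3.12 ± 0.35), the interleukin 1 receptor antagonist, and Krt7 (1.88 ± 0.17) rose. Of the 19 intestinal stem cell markers, 12 rose and 2 fell (13 and 2 adjusted over the list alone), and camera called the list higher (adjusted p = 0.000206, 0.11 with an estimated correlation). Of the 28 Wnt targets, 13 rose and 3 fell (14 and 4 adjusted over the list alone), and camera called the list higher (adjusted p = 0.00325, 0.151 with an estimated correlation). Rnf43 (1.76 ± 0.12) and Msi1 (1.49 ± 0.15) rose, and Clca3b (-1.36 ± 0.23) fell. Camera also called higher the translation initiation and elongation factors (12 of 19, 12 alone) and hypoxia and angiogenesis genes (5 of 17, 5 alone), with adjusted p between 0.000227 and 0.0266, and adjusted p = 0.0797 to 0.174 with an estimated correlation. Ddit4 (1.57 ± 0.22), an mTORC1 inhibitor, and Slc2a1 (1.01 ± 0.08) rose. Of the 24 amino acid transporters, 9 rose and 8 fell (10 and 9 adjusted over the list alone), and camera did not call the list (adjusted p = 0.797). Slc1a4 (1.76 ± 0.12) rose and Slc36a1 (-2.57 ± 0.37), a lysosomal transporter, fell.

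Of the 29 absorptive enterocyte markers, 19 fell (19 adjusted over the list alone), and camera called the list lower (adjusted p = 4.49e-08, 0.0697 with an estimated correlation). Anpep (-1.88 ± 0.14) and Slc2a5 (-1.54 ± 0.36), the fructose transporter, fell. Abcg2 (-2.41 ± 0.23), an efflux pump, and Cyp2c65 (-2.33 ± 0.34) fell. Of the 18 goblet cell markers, 10 fell (10 adjusted over the list alone), and camera called the list lower (adjusted p = 8.26e-05, 0.151 with an estimated correlation). Clca1 (-1.53 ± 0.23) and Sytl2 (-1.28 ± 0.21) were lower. Of the 16 T and NK cell markers, 15 fell (15 adjusted over the list alone), and camera called the list lower (adjusted p = 4.56e-08, 0.0944 with an estimated correlation). Cd3e (-2.60 ± 0.26) and Cd3g (-2.33 ± 0.34) fell. Of the 15 B and plasma cell markers, 15 fell (15 adjusted over the list alone), and camera called the list lower (adjusted p = 4.56e-08, 0.0797 with an estimated correlation). In ApcKras 6 of these held a value at or below 0, and 10 were highest on WT 6 among WT arrays. Without such probesets (chosen after seeing the data) the B and plasma cell list had adjusted p = 1.42e-05. Whether the adjustment added to this fall was not tested. Of the 20 interferon response genes, 13 fell (13 adjusted over the list alone), and camera called the list lower (adjusted p = 6.82e-06, 0.198 with an estimated correlation). Gbp2 (-2.59 ± 0.32), a guanylate binding protein, fell. Camera also called lower the xenobiotic and retinoid metabolism genes (17 of 24, 18 alone), enteroendocrine cell markers (11 of 22, 11 alone, 5 with the batch term), macrophage and myeloid markers (10 of 16, 11 alone), MHC class II genes (6 of 8, 7 alone) and fatty acid oxidation and PPAR target genes (9 of 21, 2 rose, 9 alone, 9 and 1 with the batch term), with adjusted p between 2.43e-08 and 0.00336, and adjusted p = 0.0697 to 0.151 with an estimated correlation. Aif1 (-2.52 ± 0.16) and Itgax (-1.54 ± 0.16), of the macrophage list, fell.

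In all, 3767 genes were higher and 3341 lower, and 5504 passed with the batch term, within the batch of WT 5 to 7. All 60 named genes that passed did so with the batch term. Single gene calls ended for Ret with the mean of a gene's probesets. Of 31 lists, 23 were called, 23 passed with the batch term and 0 with an estimated correlation. The hypoxia call ended with the dimmest genes left out (0.0677). The other 8 lists gave no call, with camera adjusted p between 0.161 and 0.84. Past the threshold only under other settings were the Paneth (2, 0.00701) and amino acid transporter (1, 0.0129) lists. Signs differed for the amino acid transporters (median -0.16, mean 0.12, test up).

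**Figure D2:**
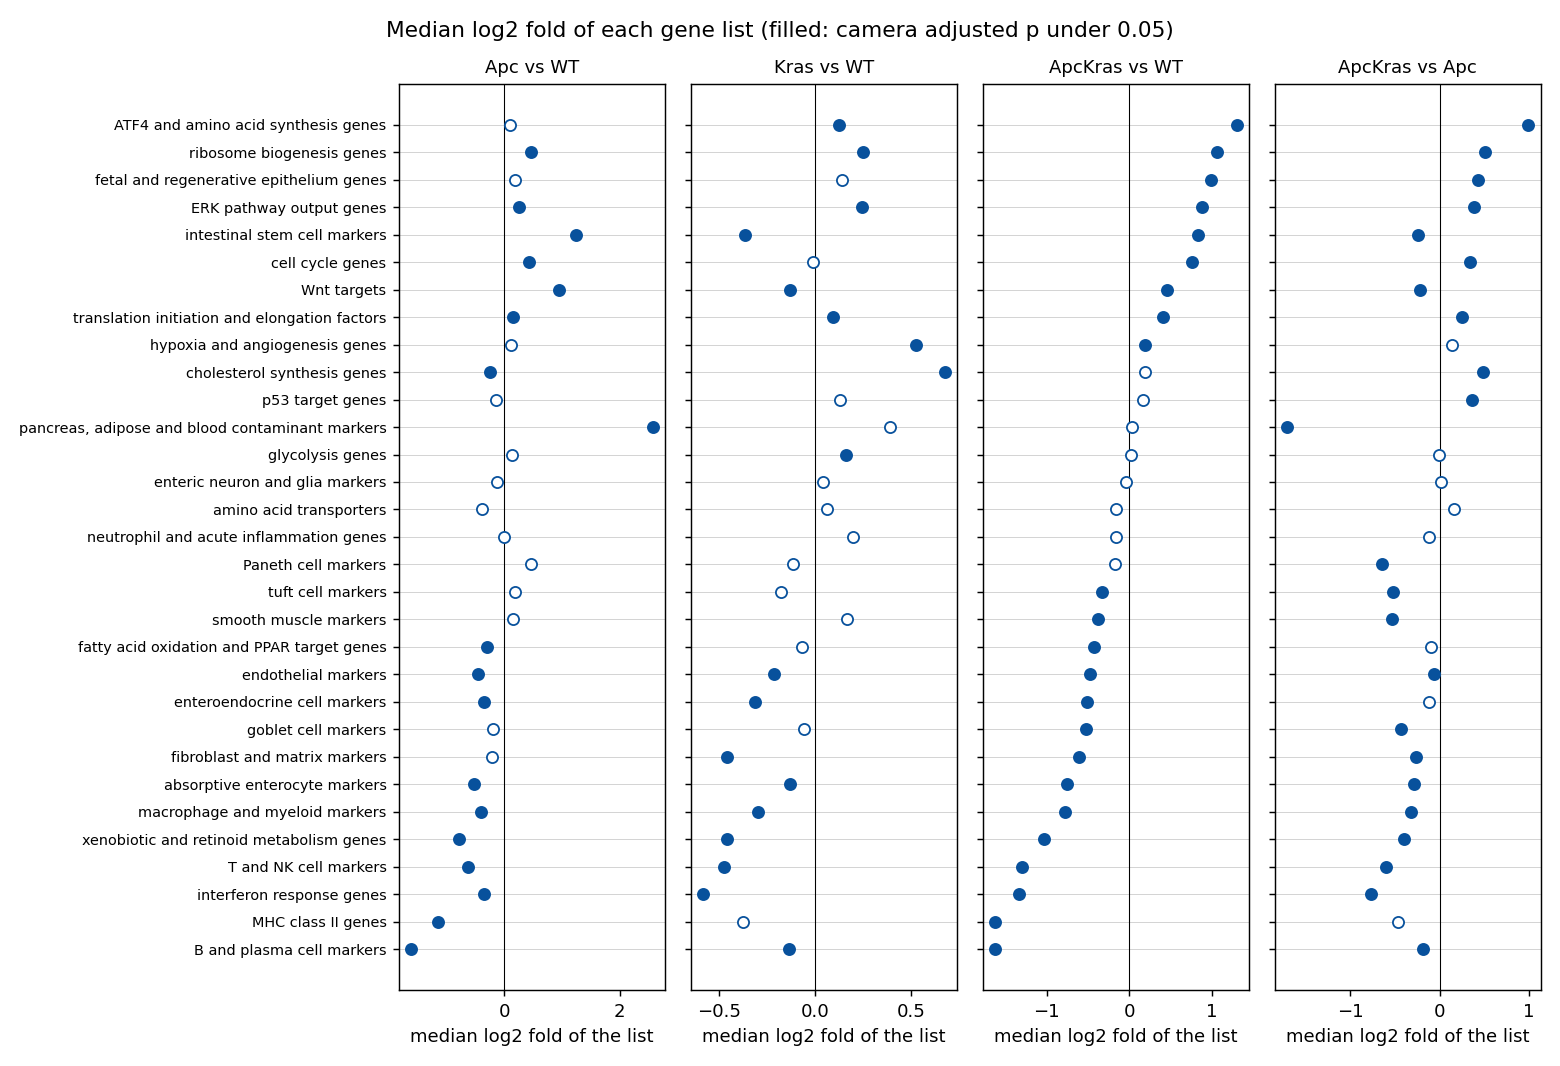
Median log2 fold of the members of each of the 31 gene lists in 4 comparisons, 1 point per list, on a common vertical axis ordered by the comparison of ApcKras with WT. Filled points passed camera at adjusted p 0.05. The ATF4 and amino acid synthesis genes had a median of 1.30 in ApcKras against WT and 0.10 in Apc against WT.

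ApcKras against Apc intestine (n = 3 each) asked what the Kras allele adds once Apc is lost. Higher were Serpinb5 (3.88 ± 0.53), Anxa10 (3.85 ± 0.21), a gastric annexin, S100a14 (3.59 ± 0.39), Anxa3 (2.97 ± 0.28) and Ddah1 (3.10 ± 0.29). Chac1 (2.31 ± 0.27), which breaks down glutathione, Psat1 (2.07 ± 0.22), Psph (1.65 ± 0.20) and Slc7a5 (1.67 ± 0.18, adjusted p = 7.61e-05) rose, and Slc3a2 had a log2 fold of 0.21 ± 0.23 (adjusted p = 0.661). Prox1 (-2.84 ± 0.20), Tnfrsf19 (-2.50 ± 0.25), Lef1 (-1.88 ± 0.26) and Nkd1 (-1.35 ± 0.12), which had been chosen as Wnt targets, fell. Bnip5 (-4.70 ± 0.52) and Mptx1 (-3.76 ± 0.52), a mucosal pentraxin, fell. The fold of Bnip5 moved by more than 1.5 times without ApcKras 1 (-4.02) or 2 (-5.46).

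Of the 23 ATF4 and amino acid synthesis genes, 18 rose (19 adjusted over the list alone), and camera called the list higher (adjusted p = 1.17e-15, 0.0115 with an estimated correlation). Of the 25 ERK pathway output genes, 10 rose (12 adjusted over the list alone), and camera called the list higher (adjusted p = 1.75e-07, 0.104 with an estimated correlation). Fosl1 (2.04 ± 0.14), Etv4 (1.47 ± 0.15) and Plaur (1.28 ± 0.21), the urokinase receptor, rose. Of the 17 fetal and regenerative epithelium genes, 10 rose and 1 fell (10 and 1 adjusted over the list alone), and camera called the list higher (adjusted p = 7.4e-05, 0.187 with an estimated correlation). Il1rn (2.83 ± 0.42) and Anxa1 (1.78 ± 0.31) rose. Of the 30 ribosome biogenesis genes, 22 rose (23 adjusted over the list alone), and camera called the list higher (adjusted p = 5.66e-14, 0.114 with an estimated correlation). Bysl (1.03 ± 0.14) and Rrp12 (0.96 ± 0.17) rose. Camera also called higher the cell cycle genes (8 of 29, 10 alone), translation initiation and elongation factors (8 of 19, 10 alone) and cholesterol synthesis genes (6 of 17, 8 alone), with adjusted p between 0.000122 and 0.0035, and adjusted p = 0.158 to 0.363 with an estimated correlation. Tpx2 (0.86 ± 0.14) rose. Of the 19 p53 target genes, 9 rose and 2 fell (11 and 2 adjusted over the list alone), and camera called the list higher (adjusted p = 0.00375, 0.187 with an estimated correlation). Sesn1 (-1.31 ± 0.14), a sestrin, fell against the list.

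Of the 28 Wnt targets, 2 rose and 7 fell (2 and 9 adjusted over the list alone), and camera called the list lower (adjusted p = 0.000491, 0.187 with an estimated correlation). Of the 19 intestinal stem cell markers, 6 fell (7 adjusted over the list alone), and camera called the list lower (adjusted p = 0.000282, 0.187 with an estimated correlation). Olfm4 (-1.42 ± 0.20) and Clca3b (-1.52 ± 0.28) fell. Of the 14 Paneth cell markers, 1 rose and 6 fell (1 and 8 adjusted over the list alone), and camera called the list lower (adjusted p = 0.00112, 0.187 with an estimated correlation). Clps (-1.61 ± 0.40), a colipase, fell, and Defa3 (1.17 ± 0.21), an alpha-defensin, rose. Camera also called lower the goblet cell markers (8 of 18, 1 rose, 10 alone), absorptive enterocyte markers (4 of 29, 8 alone), xenobiotic and retinoid metabolism genes (8 of 24, 8 alone), interferon response genes (7 of 20, 9 alone), T and NK cell markers (7 of 16, 7 alone), B and plasma cell markers (5 of 15, 5 alone), macrophage and myeloid markers (5 of 16, 1 rose, 5 alone), smooth muscle markers (3 of 13, 4 alone), fibroblast and matrix markers (2 of 14, 3 alone), tuft cell markers (2 of 15, 3 alone) and endothelial markers (3 of 14, 1 rose, 3 alone), with adjusted p between 3.64e-05 and 0.0443, and adjusted p = 0.187 to 0.322 with an estimated correlation. Rep15 (-0.93 ± 0.19), Anpep (-0.97 ± 0.17), Aif1 (-2.00 ± 0.19) and Tyrobp (-1.09 ± 0.17) fell. Of the 9 pancreas, adipose and blood contaminant markers, 4 fell (1 higher and 5 lower adjusted over the list alone), and camera called the list lower (adjusted p = 0.0023, 0.207 with an estimated correlation). Prss2 (-5.15 ± 0.75), a trypsinogen, Cpa1 (-4.45 ± 0.72), Sycn (-4.04 ± 0.78) and Cela2a (-3.81 ± 0.69) fell, the acinar genes that stood apart on Apc 1. The fold moved by more than 1.5 times without Apc replicate 1 for Clps (-1.03), Prss2 (-3.86), Cpa1 (-3.18), Sycn (-2.80) and Cela2a (-2.57), without Apc replicate 2 for Prss2 (-5.79), Cpa1 (-5.08), Sycn (-4.66) and Cela2a (-4.44) and without Apc replicate 3 for Prss2 (-5.80), Cpa1 (-5.09), Sycn (-4.67) and Cela2a (-4.43).

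The fit called 1575 genes higher and 1141 lower. With only the arrays compared it called 1065, and 2356 with the batch term, although all arrays of this comparison lie in 1 batch. All 36 named genes that passed did so with the batch term. Single gene calls ended for Anxa1, Olfm4, Clca3b, Clps, Defa3, Anpep, Tyrobp, Prss2, Cpa1, Sycn and Cela2a with only the arrays compared. Of 31 lists, 23 were called; with an estimated correlation 1 held, the ATF4 and amino acid synthesis genes. The tuft call ended without Apc 1 (0.261), with fry (0.0775) and without WT 6, Apc 1 and Kras 1 (0.275). The contaminant call ended with only the arrays compared (0.0792). The endothelial call ended without Apc 3 (0.0712), without ApcKras 2 (0.131), and with the replicate block and 8 other settings (0.0546 to 0.131). Without a call were the other 8, with camera adjusted p between 0.0524 and 0.849. Past the threshold only under other settings were the fatty acid oxidation (7, 0.00281), hypoxia (4, 0.008), MHC class II (3, 0.0284), amino acid transporter (2, 0.000979) and enteroendocrine (1, 0.0224) lists. Signs differed for the fatty acid oxidation and PPAR target genes (median -0.09, mean 0.06, test down), glycolysis genes (median -0.01, mean 0.12, test up) and enteric neuron and glia markers (median 0.02, mean -0.01, test down).

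ApcKras against Kras intestine (n = 3 and 4) asked what Apc loss does where the Kras allele is present. Cybrd1 (4.95 ± 0.37), Krt23 (3.85 ± 0.23), Piwil2 (3.52 ± 0.18), a PIWI protein of the germ line, and Ggh (2.78 ± 0.20), which trims folate polyglutamates, rose. Sox9 (2.72 ± 0.16), Rnf43 (2.11 ± 0.14), Cd44 (2.00 ± 0.16) and Msi1 (1.80 ± 0.17) rose. Slc7a5 rose by 1.51 ± 0.17 (adjusted p = 1.83e-05). Bnip5 (-5.05 ± 0.49), Slc13a1 (-4.16 ± 0.82), Fabp6 (-3.63 ± 0.70) and Slc51b (-3.26 ± 0.40), a subunit of the basolateral bile acid exporter, fell. A move of the fold by more than 1.5 times was seen without ApcKras replicate 1 for Bnip5 (-4.37), without ApcKras replicate 2 for Bnip5 (-5.82) and without Kras replicate 1 for Fabp6 (-2.72).

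Of the 19 intestinal stem cell markers, 13 rose (14 adjusted over the list alone), and camera called the list higher (adjusted p = 6.74e-07, 0.107 with an estimated correlation). Of the 28 Wnt targets, 15 rose and 2 fell (17 and 3 adjusted over the list alone, 12 and 0 with the batch term), and camera called the list higher (adjusted p = 2.8e-05, 0.11 with an estimated correlation). Of the 30 ribosome biogenesis genes, 27 rose (28 adjusted over the list alone), and camera called the list higher (adjusted p = 2.31e-14, 0.107 with an estimated correlation). Polr1a (1.26 ± 0.09), of RNA polymerase I, was an example. Of the 23 ATF4 and amino acid synthesis genes, 18 rose (18 adjusted over the list alone), and camera called the list higher (adjusted p = 1.94e-09, 0.0998 with an estimated correlation). Psat1 (2.14 ± 0.21) rose. Of the 29 absorptive enterocyte markers, 15 fell (1 higher and 17 lower adjusted over the list alone), and camera called the list lower (adjusted p = 1.54e-06, 0.164 with an estimated correlation). Slc26a3 (-1.49 ± 0.19), a chloride exchanger, and Anpep (-1.76 ± 0.15) fell. Of the 17 cholesterol synthesis genes, 8 fell (9 adjusted over the list alone, 1 with the batch term), and camera called the list lower (adjusted p = 0.00172, 0.441 with an estimated correlation). Dhcr7 (-0.84 ± 0.12), of the last steps of the pathway, fell. Camera also called higher the cell cycle genes (24 of 29, 26 alone), ERK pathway output genes (13 of 25, 1 fell, 13 alone, 8 and 1 with the batch term), fetal and regenerative epithelium genes (10 of 17, 1 fell, 10 alone, 8 and 0 with the batch term) and translation initiation and elongation factors (8 of 19, 1 fell, 8 alone, 6 and 0 with the batch term), with adjusted p between 5.33e-12 and 0.00701, and adjusted p = 0.19 to 0.217 with an estimated correlation. Kif11 (1.10 ± 0.12), a mitotic kinesin, Fosl1 (2.37 ± 0.13), Myc (1.81 ± 0.13) and Il1rn (2.54 ± 0.39) belong to them. Camera also called lower the xenobiotic and retinoid metabolism genes (12 of 24, 1 rose, 15 alone, 7 and 0 with the batch term), goblet cell markers (8 of 18, 8 alone), B and plasma cell markers (11 of 15, 12 alone, 7 with the batch term), T and NK cell markers (8 of 16, 8 alone), macrophage and myeloid markers (8 of 16, 8 alone, 4 with the batch term), fatty acid oxidation and PPAR target genes (8 of 21, 8 alone, 4 with the batch term), smooth muscle markers (2 of 13, 2 alone, 1 with the batch term), interferon response genes (9 of 20, 10 alone, 4 with the batch term), neutrophil and acute inflammation genes (4 of 18, 3 alone, 1 with the batch term), MHC class II genes (2 of 8, 2 alone, 1 with the batch term) and endothelial markers (5 of 14, 6 alone, 2 with the batch term), with adjusted p between 2.07e-05 and 0.0323, and adjusted p = 0.19 to 0.479 with an estimated correlation. Abcg2 (-2.88 ± 0.26) and Aif1 (-2.09 ± 0.18) belong to them.

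The count was 3081 higher and 3204 lower. Kras and ApcKras arrays lie in different batches, so no value within a batch can be had; with the batch as a term, which bridges them through the WT arrays, 1403 were higher and 1538 lower. Of 24 named genes that passed, 23 did so with the batch term, not Fabp6. Single gene calls ended for Fabp6 with only the arrays compared. Of 31 lists, 21 were called, 21 passed with the batch term and 0 with an estimated correlation. The neutrophil call ended without Kras 4 (0.109), and that of MHC class II with the probesets holding a value at or below 0 left out (0.0519). The endothelial call ended without ApcKras 2 (0.063), without Kras 4 (0.0882), and with the replicate block and 4 other settings (0.054 to 0.114). No call was made for 10 lists, with camera adjusted p between 0.076 and 0.938. Past the threshold only under other settings were the glycolysis (5, 0.00112), tuft (3, 0.00251), enteroendocrine (1, 0.0454) and fibroblast (1, 0.0399) lists. Signs differed for the Paneth cell markers (median 0.00, mean 0.12, test down), amino acid transporters (median -0.13, mean 0.11, test up) and p53 target genes (median 0.06, mean -0.06, test up).

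Whether the Kras effect depends on Apc was tested with the difference of differences, ApcKras minus Apc less Kras minus WT, over all 17 arrays. A value above 0 means that the log2 fold of the Kras allele was more positive with Apc deleted. It was above 0 for Cwh43 (2.95 ± 0.38), Pla2g2e (2.51 ± 0.34), a secreted phospholipase, Aqp5 (2.32 ± 0.36), a water channel of glands, Chac1 (2.13 ± 0.34), Fosl1 (2.07 ± 0.18), Anxa3 (1.88 ± 0.35) and Slc7a5 (1.12 ± 0.23, adjusted p = 0.0161). It was below 0 for Bnip5 (-4.72 ± 0.66), Mgat4c (-3.44 ± 0.71), Prox1 (-2.89 ± 0.25), Tnfrsf19 (-1.77 ± 0.31) and Nkd1 (-1.25 ± 0.15). Cpa1 (-4.70 ± 0.90) was below 0, an acinar gene high on Apc 1. The fold moved by more than 1.5 times without Apc replicate 1 for Cpa1 (-3.43), without Apc replicate 2 for Cpa1 (-5.33), without Apc replicate 3 for Cpa1 (-5.34), without ApcKras replicate 1 for Bnip5 (-4.04), without ApcKras replicate 2 for Bnip5 (-5.49) and without Kras replicate 1 for Mgat4c (-2.82).

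Of the 23 ATF4 and amino acid synthesis genes, 8 passed above 0 and 0 below (14 and 0 adjusted over the list alone, 7 and 0 with the batch term), and camera called the list higher (adjusted p = 5.46e-13, 0.025 with an estimated correlation). Trib3 (1.40 ± 0.21), a pseudokinase, and Cars (1.24 ± 0.21), a transfer RNA synthetase, were examples. Of the 17 fetal and regenerative epithelium genes, 5 passed above 0 and 0 below (9 and 1 adjusted over the list alone, 1 and 0 with the batch term), and camera called the list higher (adjusted p = 0.00049, 0.411 with an estimated correlation). Of the 25 ERK pathway output genes, 3 passed above 0 and 0 below (5 and 0 adjusted over the list alone, 1 and 0 with the batch term), and camera called the list higher (adjusted p = 0.0156, 0.411 with an estimated correlation). Of the 9 pancreas, adipose and blood contaminant markers, 0 passed above 0 and 4 below (0 and 5 adjusted over the list alone, 0 and 3 with the batch term), and camera called the list lower (adjusted p = 0.00049, 0.411 with an estimated correlation). Of the 28 Wnt targets, 0 passed above 0 and 5 below (2 and 6 adjusted over the list alone, 0 and 4 with the batch term), and camera did not call the list (adjusted p = 0.134). Of the 24 amino acid transporters, 2 passed above 0 and 2 below (4 and 2 adjusted over the list alone, 2 and 2 with the batch term), and camera did not call the list (adjusted p = 0.199). Camera also called higher the ribosome biogenesis genes (2 of 30, 9 alone, 1 with the batch term) and cell cycle genes (2 of 29, 9 alone, 0 with the batch term), with adjusted p between 1.43e-05 and 2.44e-05, and all at adjusted p = 0.411 with an estimated correlation. Fbl (0.46 ± 0.09), the fibrillarin of nucleoli, was above 0. Camera also called lower the smooth muscle markers (1 of 13, 2 alone), goblet cell markers (0 of 18, 0 alone), glycolysis genes (2 of 17, 5 alone, 0 with the batch term), neutrophil and acute inflammation genes (0 of 18, 0 alone) and Paneth cell markers (1 of 14, 1 above 0, 3 alone, 1 and 0 with the batch term), with adjusted p between 0.000384 and 0.0307, and all at adjusted p = 0.411 with an estimated correlation. Mylk (-0.81 ± 0.15), the myosin light chain kinase, and Lyz1 (-0.47 ± 0.07), the Paneth cell lysozyme, were below 0.

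Over all genes 366 were above 0 and 427 below, 793 in all. The count was 395 with the batch term, 523 without Kras replicate 2 and 523 without ApcKras replicate 3. All 18 named genes that passed did so with the batch term. Single gene calls ended for Mylk and Lyz1 with the mean of a gene's probesets, for Fbl and Lyz1 without probesets of shared sequence, for Slc7a5 and Fbl with WT 6, Apc 1 and Kras 1 left out. Of the 793, the Kras effect passed only with Apc deleted in 633, only with Apc intact in 90, in both in 48 (23 of them opposite in direction) and in neither in 22. Of 31 lists, 11 were called, and 1 held with an estimated correlation, the ATF4 and amino acid synthesis genes. With fry, which asks whether the genes of a set move on balance 1 way, 9 calls ended (adjusted p between 0.0612 and 0.147), those of the ERK, cell cycle, fetal, ribosome, glycolysis, goblet, neutrophil, smooth muscle and Paneth lists. The Paneth call ended without Apc 1 (0.101), Apc 3 (0.0615) or Kras 1 (0.075), with the replicate block (0.0577) and under 5 other settings (0.0747 to 0.174). The goblet call also ended without Kras 1 (0.051) and with WT 6, Apc 1 and Kras 1 left out (0.132). The neutrophil call ended with array weights (0.0536), without probesets of shared sequence (0.0571), without Apc 2 (0.055) and without Kras 4 (0.112). The glycolysis call ended with the dimmest genes left out (0.0793) and without Apc 1 (0.109). No call was made for the other 20 lists (camera adjusted p between 0.0661 and 0.933). Past the threshold only under other settings were the translation (10, 0.00489), p53 (9, 0.00625), enterocyte (8, 0.000131), enteroendocrine (5, 0.0247), xenobiotic (5, 0.00385), cholesterol (4, 0.00969), tuft (4, 0.00418), fatty acid oxidation (3, 0.0155), hypoxia (2, 0.0151), interferon (2, 0.0155), stem cell (1, 0.044) and T and NK cell (1, 0.0484) lists. Signs differed for the xenobiotic and retinoid metabolism genes (median 0.02, mean -0.04, test down), fatty acid oxidation and PPAR target genes (median -0.03, mean 0.00, test down), endothelial markers (median 0.09, mean -0.17, test down) and fibroblast and matrix markers (median 0.12, mean -0.05, test down).

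**Figure D3:**
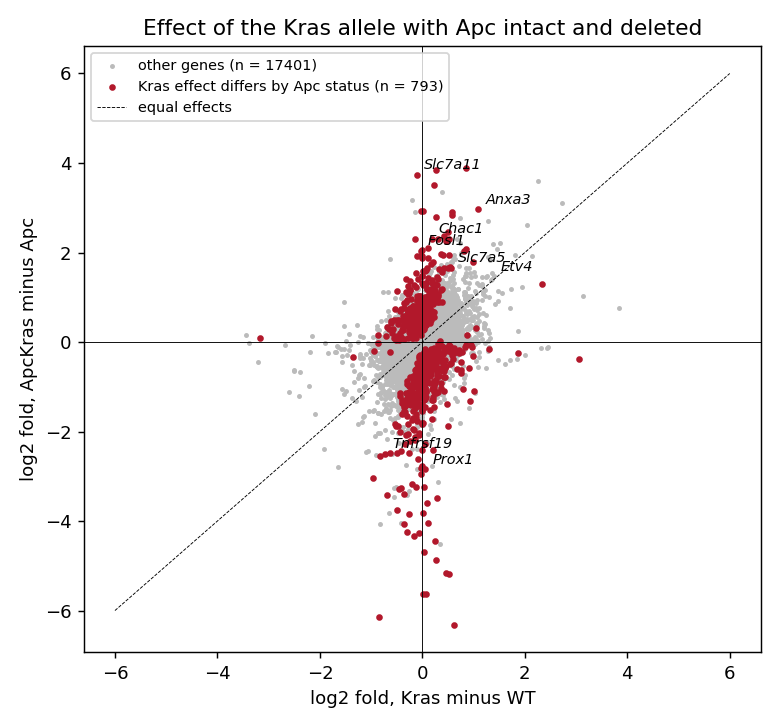
Log2 fold of each gene for Kras minus WT (horizontal) against ApcKras minus Apc (vertical), 1 point per gene. Red points are the 793 genes past adjusted p 0.05 for the difference of the effects, and the dashed line marks equal effects. Prox1 and Fosl1 lie far from that line.

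The Kras effects with Apc intact (Kras minus WT) and deleted (ApcKras minus Apc) share no array. Across genes, which are not independent replicates, their log2 folds had Pearson r = 0.346 (jackknife SE 0.0572) and Spearman rho = 0.35. Both rose past the threshold for 298 genes, against 75.9 expected if the calls were independent, and both fell for 104, against 27.5, with 23 opposite. Ddah1, Etv4, Psat1 and Slc7a5 were among those higher in both. Of the 1316 genes called in Kras intestine, 80.7% had the same sign in the second comparison. The Apc effects without the Kras allele (Apc minus WT) and with it (ApcKras minus Kras) had Pearson r = 0.675 (jackknife SE 0.0364) and Spearman rho = 0.648. Here 1469 genes rose in both, against 367 expected, 1602 fell in both, against 397, and 55 were opposite, and 92.4% of the 4426 called first had the same sign in the second. Sox9, Rnf43, Cybrd1 and Myc rose in both, and Anpep and Cd3e fell in both.

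**Figure D4:**
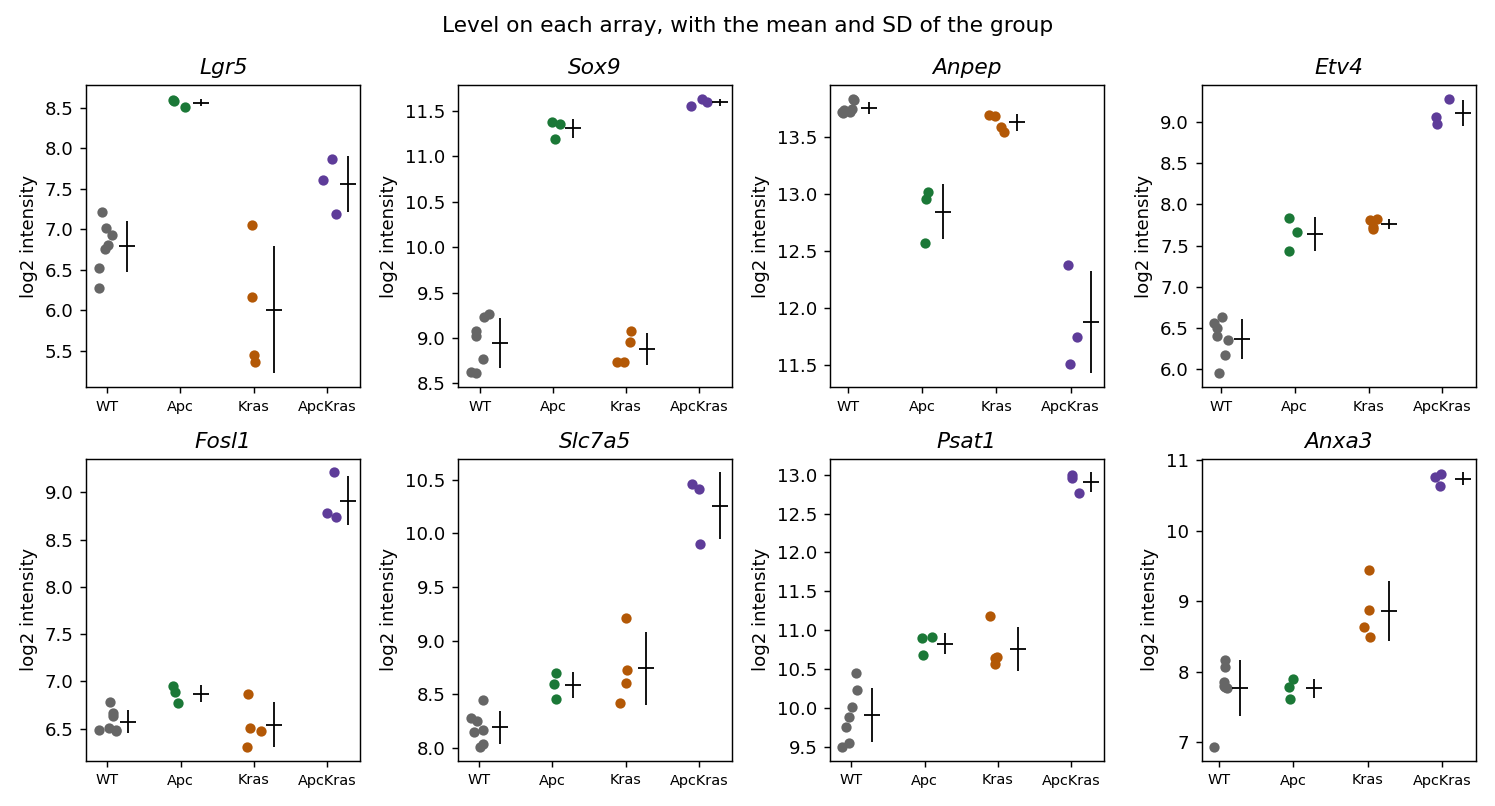
Log2 intensity of 8 genes on each of the 17 arrays, 1 panel per gene, with arrays grouped as WT (n = 7), Apc (n = 3), Kras (n = 4) and ApcKras (n = 3). Points are arrays, and the bar beside them is the mean ± SD of the group. Slc7a5 averaged 8.19 ± 0.15 in WT and 10.26 ± 0.31 in ApcKras (SD).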

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

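Chosen only after the result was seen were the tests of chance likeness of the WT arrays, of shuffled residuals, and of the batch, the deletion of Apc and a spread from Apc 1 for the acinar transcripts, and the alternatives with a batch term, a sex term or without values at or below 0.

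The means of WT 1 to 4 and of WT 5 to 7 nearly coincide. The split was found by its closeness, so its rank (1 of 35 splits as close, this one, root mean square difference 29.48, 61.13 for the next) does not test chance, which stays open for the means. Values adjusted for a batch on the linear scale are a candidate explanation. Of Kdm5d and Uty, silent in females, the smaller distance of ApcKras 2 from the females of the first batch was 64.6 times their SD, with Uty at -43.33 against a mean of 79.92. Within-batch fits stand beside the results, Kras and ApcKras share no batch, and no biological explanation was tested.

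The Kras allele changed 2716 genes with Apc deleted and 1316 with Apc intact, and 793 passed the test of the difference. The first counts compare groups of unlike size (3 with 3 and 4 with 7 arrays), and with only the arrays compared they were 1065 and 982, so that the gap depends on this choice. For the 793, 1 deviating Kras array (794 without Kras 1) or sex (717 with a sex term) was argued against as the whole cause. Leaving out probesets with a value at or below 0 (767) cannot decide, as only 154 hold one. Without Kras replicate 2 or ApcKras replicate 3 the count was 523. Of 100 orders of the residuals of a fit of additive Apc and Kras effects, 1, the real one, gave as many (highest other 11). This argues against chance only for independent arrays. Splits of the arrays within each Apc status decide nothing here. Of 100, 12 gave as many (highest other 1847), all among the 14 that kept the ApcKras arrays together and so the whole effect of ApcKras against Apc, a structure of the samples, and with these arrays parted the highest was 4. With the batch term 395 genes passed, from Kras against WT 1 to 4 and ApcKras against Apc, each within a batch as read from the values. A log2 shift shared by all arrays of a batch cancels there, so it does not account for these 395. Effects of the adjustment on single groups, and a dependence on Apc, which the design names, stay open.

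Pancreatic acinar transcripts were higher in the Apc group, with a median log2 fold of 4.36 over 5 members (3.09 without Apc 1). Within the batch the median was 4.67, no test of a batch, since the WT means nearly coincide. Pancreas tissue in a sample may be the source. Of 11 acinar genes (Cela1 also a member), 10 were higher on Apc 1 than on every WT array. Cpb1 was at 10010 against at most 38.21. Spink1, high in WT (median 9605), was at 7938. On Apc 2 and Apc 3 the adjustment could have spread values of Apc 1, since over 13 acinar genes their median absolute log2 ratio was 0.025 against 0.198 for 9495 genes of like intensity, 0% of 10000 random sets were as close, and Apc 2 held 4.66% to 6.42% of the rise on Apc 1. Deletion of Apc whatever the Kras allele was argued against, since in ApcKras intestine, which carries it too, the median log2 fold of the members against WT was -0.09, with Cpa1 at 6.05 ± 0.22 log2 intensity (SD, n = 3) and Cpb1 at an intensity of at most 3.007. An effect of the deletion only without the Kras allele stays open, as untested.

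For the other counts, splits of the same arrays into groups of the same sizes were tested. Of 100 drawn in each case, 1 gave as many, the real one. This held for Apc against WT (4426 genes, highest other 35), Kras against WT (1316, 4) and ApcKras against WT (7108, 12). For ApcKras against Kras it was 1 of 35 (6285, 2818). There the highest other set Kras 1 to 3 against the rest. The adjustment may have shared values within a group, so these splits do not exclude chance. ApcKras against Apc allows 10 splits, too few for a share under 0.05; the real one gave 2716 and the highest other 4.

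A single array stood far from the others of its group (Dixon's criterion, groups of 4 to 10) for 24 of 286 combinations of a named gene and a group, where chance gives about 1 in 20. Of these, 11 were on Kras 1 and 7 on Kras 4. In log2 intensity, Kras 1 was highest of its group for Abcg2 (12.13), Fabp6 (13.82), Fgfrl1 (9.35), Il1rn (9.03), Lyz1 (13.79) and Nsdhl (10.60) and lowest for Adh6a (11.41), Car9 (10.64), Ggh (7.91), Reg3a (6.87) and Slc2a5 (8.99). Kras 4 was highest of its group for Ddit4 (12.12), Psat1 (11.18) and Wdr43 (10.44) and lowest for Ascl2 (5.00), Col6a4 (6.23), Csf1r (10.29) and Dhcr7 (10.77). Elsewhere stood Abcg2 (11.19, highest on WT 5), Aif1 (10.31, highest on WT 6), Anxa3 (6.93, lowest on WT 7), Cd8b1 (6.31, highest on Kras 3), Cyp2c65 (10.64, lowest on WT 2) and Sycn (8.19, highest on WT 3).

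The Kras effect differed by Apc status, by the test of the difference itself, for 42 of the 143 genes named. The log2 difference was above 0 for Anxa10 (3.58), Serpinb5 (3.02), Cwh43 (2.95), Pla2g2e (2.51), Aqp5 (2.32), Il1rn (2.25), Chac1 (2.13), Fosl1 (2.07), Anxa3 (1.88), Krt23 (1.52), Trib3 (1.40), Cars (1.24), Psat1 (1.23), Psph (1.22), Slc7a5 (1.12), Defa3 (1.09), Plaur (1.00), Tpx2 (0.64), Polr1a (0.55), Fbl (0.46) and Chgb (0.42). It was below 0 for Prss2 (-5.61), Bnip5 (-4.72), Cpa1 (-4.70), Cela2a (-3.83), Cela3b (-3.78), Mgat4c (-3.44), Mptx1 (-3.26), Gzmb (-2.95), Prox1 (-2.89), Abcg2 (-1.86), Tnfrsf19 (-1.77), Aif1 (-1.57), Lef1 (-1.37), Nkd1 (-1.25), Tek (-1.14), Sesn1 (-1.02), Tyrobp (-0.89), Anpep (-0.85), Mylk (-0.81), Pdk1 (-0.72) and Lyz1 (-0.47). Of these, Anxa10, Gzmb, Prss2 and Tek had arrays at the floor, on which their values depend. The difference moved by more than 1.5-fold without Apc 1, where acinar genes were highest, for Prss2 (-4.32), Cpa1 (-3.43), Cela2a (-2.59) and Cela3b (-2.56). Without Apc 2 or Apc 3 these lay further below 0 (-4.38 to -6.26). Bnip5 and Mgat4c moved as far without other arrays. Calls ended without an array for 15 (Anpep, Cela2a, Cela3b, Chgb, Defa3, Il1rn, Lef1, Pdk1, Plaur, Polr1a, Psat1, Serpinb5, Tek, Tpx2 and Tyrobp).

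Probesets without a single gene, which no comparison used, were tested alike, 10092 in number. Past the threshold were 840 in Apc against WT, 205 in Kras against WT, 1504 in ApcKras against WT, 317 in ApcKras against Apc, 1372 in ApcKras against Kras and 92 for the difference of Kras effects.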

How the results depend on the processing

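The alternatives with a batch term, a sex term, floors of 16 and 64, probesets with a value at or below 0 left out, and WT 6, Apc 1 and Kras 1 left out were chosen after seeing the data. Counts of genes past the threshold moved by more than 1.5 times as follows, and apart from the replicate block no other alternative moved one so far. With a log2 fold of at least 1, which keeps fewer genes by construction, the counts were Apc against WT (659), Kras against WT (108), ApcKras against WT (1719), ApcKras against Apc (613), ApcKras against Kras (1387) and the difference of Kras effects (264), and at an adjusted p of 0.01 Apc against WT (2552), Kras against WT (389), ApcKras against Apc (1258), ApcKras against Kras (4168) and the difference of Kras effects (234). With the batch term they were Apc against WT (2626), Kras against WT (434), ApcKras against Kras (2941) and the difference of Kras effects (395), with a sex term Kras against WT (711) and with only the arrays compared ApcKras against Apc (1065); the cause was not tested. Leaving out each array gave 3236 to 4346 for Apc against WT, 729 to 1348 for Kras against WT (lowest without Kras replicate 4), 6047 to 6909 for ApcKras against WT, 1855 to 2252 for ApcKras against Apc, 5204 to 6016 for ApcKras against Kras and 523 to 849 for the difference (lowest without Kras replicate 2 or ApcKras replicate 3), each with fewer samples. The correlation across genes lay at 0.291 to 0.355 for the Kras effects and 0.647 to 0.68 for the Apc effects, and the number of lists called at 112 to 123, against 114 of 186 with all arrays.

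The replicate numbers do not pair the samples. Of 19 pairs of arrays with the same number in different groups, 0 had a correlation of their deviations from the group means over 0.1 (median 0.0023, against 0.00159 over 84 pairs with different numbers), and 2 of 14 arrays correlated best with a same-numbered one. With the replicate number as a block the counts were Apc against WT (2650), Kras against WT (213) and the difference of Kras effects (216), and the calls of 33 named genes and 3 lists ended; the cause was not tested.

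With an estimated correlation, camera called 6 lists, 2 in Apc against WT, 2 in Kras against WT, 1 in ApcKras against Apc and 1 for the difference; the cause was not tested. Of 114 list calls, 6 kept direction and side of the threshold under all alternatives run, and of 207 calls of named genes 158 did. Over all alternatives, 5059 list values kept both, 188 no longer passed, 147 newly passed and 0 turned direction. For values of named genes the numbers were 5335, 89, 1 and 1. The last was Apc in Apc vs WT, at -0.17 with every probeset alone (adjusted p = 0.0436), where another probeset than the brightest passed. Signal over background limits genes near the floor, since 13.1% of the values were at it and falls to it are bounds.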

Other observations

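Lists of fibroblast, smooth muscle, endothelial and tuft cell markers were called lower in ApcKras than in WT intestine (n = 3 and 7), and that of enteric neurons and glia was not called. Of the 14 fibroblast and matrix markers, 9 fell (9 adjusted over the list alone), and camera called the list lower (adjusted p = 0.000701, 0.214 with an estimated correlation). Col3a1 (-1.22 ± 0.18), a fibrillar collagen, and Pdgfra (-0.87 ± 0.12), a growth factor receptor of mesenchymal cells, fell. Of the 13 smooth muscle markers, 5 fell (5 adjusted over the list alone), and camera called the list lower (adjusted p = 0.0126, 0.53 with an estimated correlation). Mylk (-1.01 ± 0.10) and Lmod1 (-0.80 ± 0.19), of the contractile apparatus, fell, and the call of the list ended without ApcKras replicate 3 (0.0552). Of the 14 endothelial markers, 8 fell (1 higher and 9 lower adjusted over the list alone, 5 with the batch term), and camera called the list lower (adjusted p = 0.00109, 0.0697 with an estimated correlation). Kdr (-1.25 ± 0.17), the main receptor for vascular endothelial growth factor, and Pecam1 (-0.77 ± 0.15) fell. Of the 15 tuft cell markers, 1 rose and 5 fell (1 and 5 adjusted over the list alone), and camera called the list lower (adjusted p = 0.0266, 0.53 with an estimated correlation). Hpgds (-1.40 ± 0.21), a prostaglandin synthase, fell.

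Members of other lists parted in ApcKras against WT. Of the fatty acid oxidation and PPAR target genes, Ppargc1a (-1.44 ± 0.23), a coactivator of mitochondrial genes, and Ehhadh (-1.22 ± 0.17), of peroxisomes, fell, while Acadl (1.03 ± 0.19), a mitochondrial dehydrogenase, rose. Of the 19 p53 target genes, 8 rose and 4 fell (8 and 4 adjusted over the list alone), and camera did not call the list (adjusted p = 0.396). Tnfrsf10b (1.56 ± 0.17), a death receptor, and Aen (1.07 ± 0.13), a nuclease, rose, while Sesn1 (-2.11 ± 0.12) and Fas (-2.18 ± 0.29), another death receptor, fell. Of the 13 enteric neuron and glia markers, 1 rose and 2 fell (1 and 2 adjusted over the list alone), and camera did not call the list (adjusted p = 0.619). S100b (0.87 ± 0.16), a protein of glia, rose and Ret (-0.84 ± 0.21), the receptor tyrosine kinase of enteric neurons, fell, a call that ended with the mean of its probesets (0.0502).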
